A study of Mus musculus with 6 samples.

How the data were processed

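ChIP-seq was performed on feeder-free E14Tg2A mouse embryonic stem cells grown on gelatin with 20% serum and leukemia inhibitory factor. Per the labels' protocols, cells were crosslinked in 1% formaldehyde for 10 min and sonicated for 14 min, and libraries were prepared with a commercial DNA sample kit. The 6 samples comprised 1 immunoprecipitation each for Ring1B, Cbx7, Suz12 and RYBP and 2 with rabbit IgG. Samples were assigned to groups by the target that their description names, and each peak list was assigned to the only sample with its target. The labels mark the Suz12 library and 1 of the IgG libraries as first submitted under other sample records.

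The authors deposited 1 peak list per target, and the other values in them are peak start and end positions in base pairs, with no height, score, fold or p per peak. Per the submitters' processing notes, Bowtie 0.12.7, MACS 1.3.7.1 and genome build mm9 were used. The notes list these names without their roles. The control library, the threshold, the handling of duplicate reads and whether replicates were pooled are not given in the sources used here. The name column of the lists carries the number 5 for RYBP and 10 for the other 3 targets, and its meaning is not stated. If it is a calling threshold, the RYBP list was called at another stringency than the other lists, which would change the number of its peaks and every share that involves RYBP. The width of a called peak can depend on the strength of the signal as well as on the extent of binding. No peak of a list overlapped another peak of the same list, and all peaks lay on chromosomes 1 to 19, X or Y.

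Read depth is unknown because the lists hold no counts. The precision of each share is therefore given as a 95% Wilson interval over peaks, which covers the sampling of peaks and not the variation between libraries. Since neighbouring peaks are not independent, the 1909 occupied 1-Mb blocks of the Ring1B list were also resampled 1000 times. This gave block intervals of the Cbx7 and RYBP odds ratio on all Ring1B peaks, of its pooled form and of unstratified differences between classes. The other odds ratios have exact intervals only, which treat peaks as independent.

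Peaks were called overlapping when they shared at least 1 bp. Each pair of lists was compared with 1000 seeded rotations of the second list along each chromosome, taking as its length the largest peak end in any list. Rotation keeps the spacing of peaks but not their preference for promoters or for well mapped sequence, so the fold over rotation is not a fold over accessible sites. Ring1B peaks were divided into 4 classes by overlap with Cbx7 and RYBP. Classes were compared by two-sided Fisher's exact tests for Suz12 and by two-sided permutation tests of the difference of median width with 100000 resamples, each adjusted by the Benjamini-Hochberg method within its family. The share of peaks on X was compared between lists by Fisher's exact tests, which treat the lists as separate samples although they share sites. Intervals of odds ratios from single tables are exact conditional 95% intervals, and values pooled over strata are Mantel-Haenszel estimates. A difference was called at an adjusted p below 0.05. Analyses were run with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures with matplotlib 3.10.9.

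The functions were tested on simulated data. A list built from 30.3% of the 6982 Ring1B peaks was recovered at 30.3%. None of 40 rotated copies of the Cbx7 list was called against Ring1B. For a planted odds ratio of 0.5 between 2 subunits whose frequency also rose with peak width, the stratified estimate was 0.474 and the unstratified one 1.24. This simulation made width the driver of both subunits, and the reverse, in which a subunit widens the peak, was not simulated.

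The tests between lists and classes, their alternatives and the rule for naming items were fixed before the data were examined. The merged regions, the tests that split a list by overlap with another and count a further one, the share of Ring1B peaks of X with each subunit and the block resampling were added after the data were seen. Without gene assignment the rule names, in place of genes, the 5 peaks of each list and of each Ring1B class with the highest value of the authors, and the 5 windows of 200 kb with the most sequence covered by Ring1B. The lists give no such value, so peak width was used, and this change was made after the data were seen. No annotation of mm9 was used here, so peaks were not assigned to genes, and the intended tests of gene lists and of GC and CpG content were not run. Before the data were examined, the alternatives chosen were an overlap of at least 50% of the shorter peak, a distance of up to 1 kb, leaving out X and Y, shifting each peak by up to 1 Mb in place of rotation, and merging peaks within 1 kb. Alternatives that rank peaks by p or score were not possible, and peaks of at least median width in each list and equal list lengths by width were added in their place. Stratification by quintiles of Ring1B peak width and leaving out the 21 windows of 1 Mb with 20 or more RYBP peaks were also added after the data were seen. With 1 library per target, leaving out a replicate was not possible. Coordinates are printed as the lists give them.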

Results

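Genome-wide binding of 4 Polycomb subunits was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in wild-type E14Tg2A mouse embryonic stem cells, a line of the 129/Ola strain grown with leukemia inhibitory factor. Ring1B is the catalytic E3 ubiquitin ligase of Polycomb repressive complex PRC1. Cbx7 is the chromodomain subunit of canonical PRC1 and binds trimethylated lysine of histone H3. RYBP is the subunit of variant PRC1 complexes, which lack Cbx proteins. Suz12 is a core subunit of PRC2, the complex that writes the histone mark read by Cbx7. Each target had 1 library, and 2 further libraries were made with a non-specific rabbit IgG and were not analysed here. The comparisons addressed how far the binding sites of the Cbx7 and RYBP forms of PRC1 coincide with Ring1B, with PRC2 and with each other.

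The Suz12 list held 8054 peaks, the Ring1B list 6982, the RYBP list 6872 and the Cbx7 list 2754. Cbx7 peaks were the widest, with a median of 1941 bp (quartiles 1375 to 2673 bp). Ring1B peaks had a median width of 1639 bp and Suz12 peaks of 1584 bp. RYBP peaks were the narrowest, with a median of 1219 bp, and varied least, with quartiles of 1042 and 1495 bp. Suz12 peaks covered 15.6 Mb of the genome, Ring1B peaks 14.1 Mb, RYBP peaks 9.21 Mb and Cbx7 peaks 6.31 Mb. The lists hold positions only, so the sequencing depth and the height of each peak are unknown. With 1 library per target, no difference between targets has a replicate check. Intervals and p-values below describe the peaks of these lists, and neighbouring peaks are not independent.

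The question asked first was how often 2 subunits shared a site. Most Cbx7 peaks lay on sites of Ring1B and of Suz12: 92.1% overlapped Ring1B (2536 of 2754 peaks, 95% Wilson interval 91.0 to 93.0%) and 92.2% overlapped Suz12 (91.1 to 93.1%). Of the Ring1B peaks, 81.9% overlapped Suz12 (81.0 to 82.8%), 35.3% overlapped Cbx7 (34.2 to 36.4%) and 33.0% overlapped RYBP (31.9 to 34.1%). Of the Suz12 peaks, 72.4% overlapped Ring1B, 31.3% overlapped Cbx7 and 25.9% overlapped RYBP. The RYBP list stood apart: 34.6% of its peaks overlapped Ring1B (33.5 to 35.8%), 31.5% overlapped Suz12 and 12.2% overlapped Cbx7. Each of the 12 directed overlaps exceeded the values from 1000 random rotations of the second list along its chromosomes, which averaged between 0.398% and 1.27% (two-sided p = 0.002 by this permutation test, the smallest it can give, and 0.002 after Benjamini-Hochberg adjustment over 12 tests). Enrichment over rotation was 81.7-fold for Cbx7 peaks on Ring1B and 36.5-fold for RYBP peaks on Ring1B. Lists made equal in length by keeping the widest 2754 peaks of each raised the share of Ring1B peaks with Cbx7 to 67.7% and that of Suz12 peaks with Cbx7 to 65.5%, and lowered the share of Cbx7 peaks with RYBP from 28.9% to 16.0%, with Ring1B to 72.9% and with Suz12 to 69.8%. In the narrowest quintile of Cbx7 peaks, 64.7% overlapped Ring1B (60.6 to 68.5%).

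**Figure D1:**
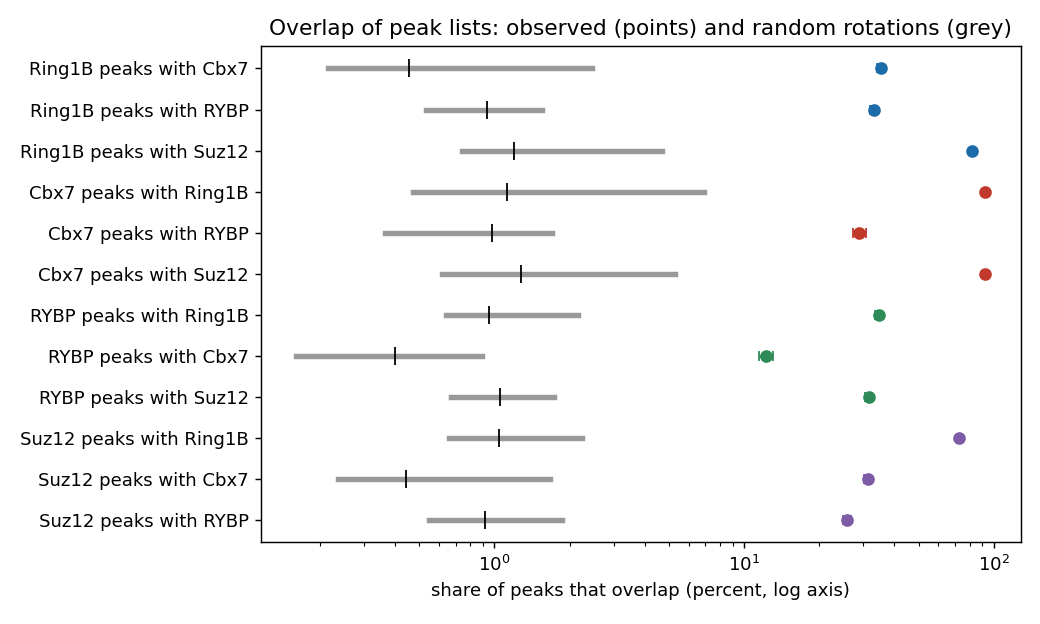
Share of the peaks of one list that overlap a peak of another by at least 1 bp (points, percent on a log axis, with 95% Wilson intervals), and the mean and full range over 1000 random rotations (black ticks and grey bars). All 12 observed shares lie above the whole range of the rotations.

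Merging the 4 lists gave 13390 separate regions. The most frequent kind, 4250 regions or 31.7%, held a RYBP peak and no other. Ring1B with Suz12, without Cbx7 or RYBP, occupied 2099 regions, and Ring1B with Suz12 and Cbx7 occupied 1533. Ring1B with Suz12 and RYBP occupied 1049 regions, and all 4 subunits shared 789. Ring1B with RYBP but without Suz12 occupied 446 regions, whereas Ring1B with Cbx7 but without Suz12 occupied 10. Cbx7 alone was found in 201 regions with a median width of 619 bp, and no region held Ring1B, Cbx7 and RYBP without Suz12. Regions with all 4 subunits were the widest, with a median of 3242 bp, compared with 2853 bp for Ring1B, Cbx7 and Suz12 and 2049 bp for Ring1B, RYBP and Suz12. A merged region spans all its peaks, so a further list can only widen it, and this order of widths was not tested.

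**Figure D2:**
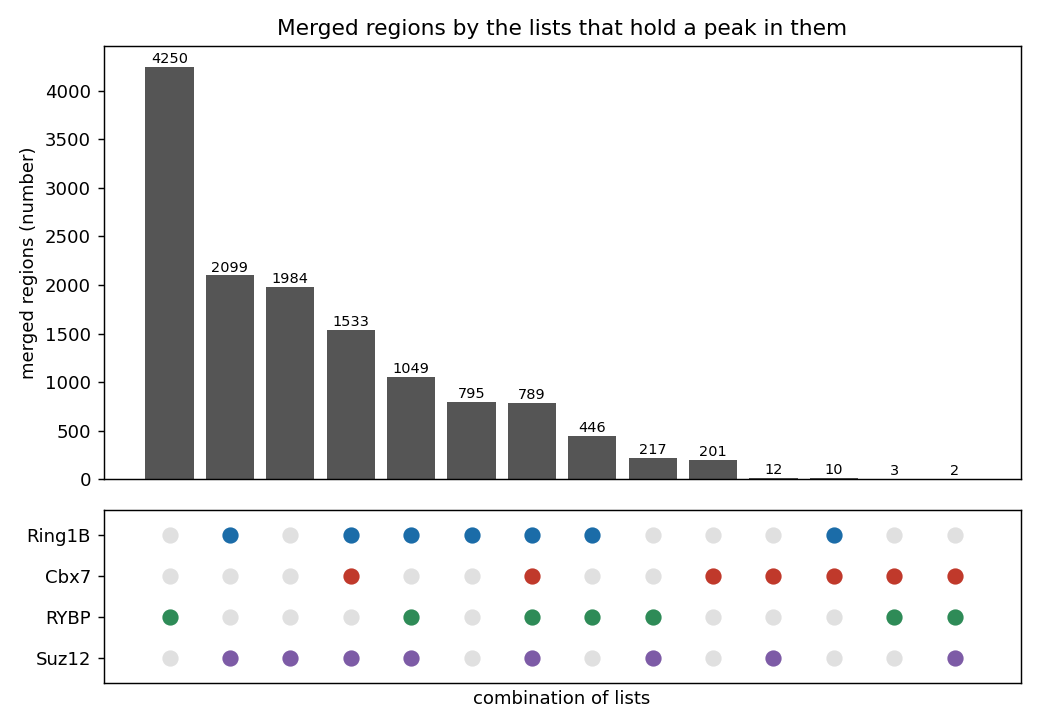
Number of merged regions (bars, linear axis from 0) for each combination of lists with a peak in the region (coloured dots below). Regions with RYBP alone number 4250, and regions with Ring1B and Suz12 but neither Cbx7 nor RYBP number 2099.

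The Cbx7 and RYBP forms of PRC1 were then compared on Ring1B peaks. Of the 6982 Ring1B peaks, 793 carried both subunits (11.4%), 1670 carried Cbx7 without RYBP (23.9%), 1511 carried RYBP without Cbx7 (21.6%) and 3008 carried neither (43.1%). RYBP was found on 32.2% of the Ring1B peaks with Cbx7 and on 33.4% of those without. The number with both, 793, compares with 813 expected if the 2 subunits were placed independently on the Ring1B peaks. The odds ratio was 0.945 (exact 95% interval 0.850 to 1.05, p = 0.299, two-sided Fisher's exact test), and resampling 1-Mb blocks of the genome gave an interval of 0.850 to 1.06, so no association was detected over all Ring1B peaks. Both subunits were more frequent on wider Ring1B peaks. Cbx7 was found on 5.44% of the narrowest quintile of Ring1B peaks and on 84.4% of the widest quintile, and RYBP on 20.2% and 42.0%. Within every quintile, RYBP was less frequent where Cbx7 was present: 6.58% against 21.0% in the narrowest quintile, 20.5% against 38.7% in the middle quintile and 39.3% against 56.4% in the widest. The odds ratio pooled over the quintiles, a stratification chosen after the data were seen, was 0.480 by the Mantel-Haenszel method (block interval 0.413 to 0.564). In two-sided Fisher's exact tests, counting peaks within 1 kb of each other as shared gave 0.840 (p = 8.4e-04), and lists made equal in length by width gave 0.606 (p = 6.3e-08). On Suz12 peaks, without stratification by width, RYBP was found on 31.7% of those with Cbx7 and 23.3% of those without (odds ratio 1.52, exact 95% interval 1.37 to 1.69), but this set includes 2224 peaks without Ring1B, of which 10.1% carried RYBP and 0.764% carried Cbx7.

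**Figure D3:**
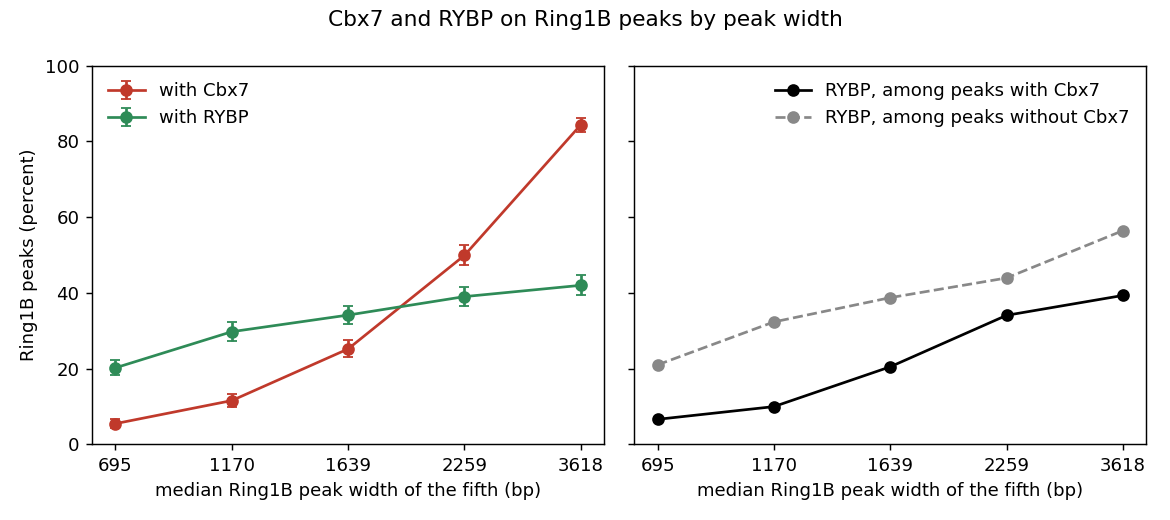
Share of Ring1B peaks with Cbx7 and with RYBP (left, percent, with 95% Wilson intervals) and share with RYBP among Ring1B peaks with and without Cbx7 (right), in quintiles of Ring1B peak width labelled by median width in bp. The share with Cbx7 runs from 5.44% to 84.4%, and in each quintile RYBP is less frequent on peaks with Cbx7.

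Suz12 was more frequent on Ring1B peaks with Cbx7 than on the other Ring1B peaks. All 793 Ring1B peaks with both Cbx7 and RYBP overlapped Suz12 (95% Wilson interval 99.5 to 100%), as did 99.1% of those with Cbx7 without RYBP (98.5 to 99.5%). Suz12 was present on 70.2% of Ring1B peaks with RYBP without Cbx7 (67.8 to 72.4%) and on 73.6% of those with neither (72.0 to 75.1%). The difference between the Cbx7 and the RYBP class was 28.9 percentage points (block interval 26.6 to 31.4, adjusted p = 1.8e-139, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 6 tests). It was 17.8 points within quintiles of peak width, and 11.3 points when each list kept only its peaks of at least median width. The class with RYBP alone lay 3.42 points below the class with neither (difference -3.42, block interval -6.34 to -0.66, adjusted p = 0.016, Fisher's exact test). By the same exact test, that direction turned with peaks of at least median width (1.40 points, adjusted p = 0.438) and with equal list lengths (8.19 points, adjusted p = 0.012). Both settings shorten the RYBP and Suz12 lists as well, so the classes are not those of the whole lists. Within width quintiles the difference was -13.9 points. The difference of 0.898 points between peaks with both subunits and with Cbx7 alone (adjusted p = 0.005 in Fisher's exact test) was 0.279 points and no longer called within width quintiles, and 4.50 points with equal list lengths. The remaining differences kept their direction and stayed called, but were smaller among wide peaks and within width quintiles. Within quintiles, peaks with both subunits exceeded those with RYBP alone by 8.09 points and those with neither by 3.94 points, compared with 29.8 and 26.4 points without stratification, and Cbx7 alone exceeded neither by 8.79 points compared with 25.5. Differences within quintiles weight the quintiles by the peaks of each pair, so they are not on a common scale. In the widest quintile 99.9% of Ring1B peaks overlapped Suz12, and 98.7% in the next widest, which leaves little room for a difference there.

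Ring1B peak width also differed between the classes. Peaks with Cbx7 and RYBP had a median width of 2916 bp (quartiles 2307 and 3958 bp), those with Cbx7 without RYBP 2494 bp, those with RYBP without Cbx7 1502 bp and those with neither 1174 bp. Ring1B peaks with Cbx7 without RYBP exceeded those with RYBP without Cbx7 by 992 bp (block interval 918 to 1097 bp). Ring1B peaks with both subunits exceeded those with Cbx7 alone by 422 bp (326 to 571 bp). The remaining differences ranged from 329 bp between RYBP alone and neither to 1743 bp between both and neither. All 6 differences of medians gave p = 1e-05 in a two-sided permutation test with 100000 resamples, the smallest it can give, and 1e-05 after adjustment over the 6 tests. The classes are defined by overlap, so these differences restate the rise of both subunits with Ring1B peak width given above. They are not separate support for it.

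Most RYBP peaks lay outside Ring1B sites. Of the 6872 RYBP peaks, 4491 did not overlap a Ring1B peak. Of these, 5.30% overlapped Suz12 (238 peaks, 95% Wilson interval 4.68 to 5.99%) and 0.111% overlapped Cbx7 (5 peaks). Of the 2381 RYBP peaks on Ring1B, 81.0% overlapped Suz12 (79.4 to 82.5%) and 35.1% overlapped Cbx7 (33.2 to 37.0%). The odds ratio for Suz12 was 76.3 (exact 95% interval 64.4 to 90.4). RYBP peaks outside Ring1B had a median width of 1181 bp, and those on Ring1B of 1305 bp. Of the 2224 Suz12 peaks without Ring1B, 10.1% overlapped RYBP and 0.764% overlapped Cbx7, compared with 32.0% and 43.0% of the 5830 Suz12 peaks with Ring1B.

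Broad regions were described by position, in mm9 coordinates as listed. Windows of 200 kb were ranked by the sequence that Ring1B peaks covered. A window on chromosome 11 from 96000000 to 96200000 held 28 Ring1B peaks covering 38.6% of its length and 39 Suz12 peaks covering 41.2%, while 17 Cbx7 peaks covered 20.5% and 2 RYBP peaks covered 1.39%. A window on chromosome 6 from 52000000 to 52200000 was covered to 36.6% by 18 Ring1B peaks, to 35.1% by Suz12, to 27.1% by Cbx7 and to 6.17% by 9 RYBP peaks. A window on chromosome 2 from 74400000 to 74600000 was covered to 35.3% by 22 Ring1B peaks, to 34.97% by Suz12, to 27.2% by Cbx7 and to 1.10% by 2 RYBP peaks. The other 2 windows among the 5 most covered, on chromosome 8 from 126000000 and on chromosome 6 from 47600000, owed their coverage to a few very wide peaks. The widest peak of the Ring1B, Cbx7 and Suz12 lists was nearly the same interval on chromosome 8, 126060836 to 126148721 in the Ring1B list, which spans 87.9 kb. The next widest Ring1B peaks, on chromosome 6 from 47686949 to 47723612 and from 47600629 to 47637156, spanned 36.7 and 36.5 kb and were also shared with Cbx7 and Suz12. None of these 3 peaks overlapped a RYBP peak. The chromosome 8 peak started at 126060836, 126060947 and 126060855 in the Ring1B, Cbx7 and Suz12 lists, so its edge nearly coincided between them. Without read counts, broad binding at these 3 peaks cannot be told apart from segments with more copies in the libraries than in their control, which was not tested.

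**Figure D4:**
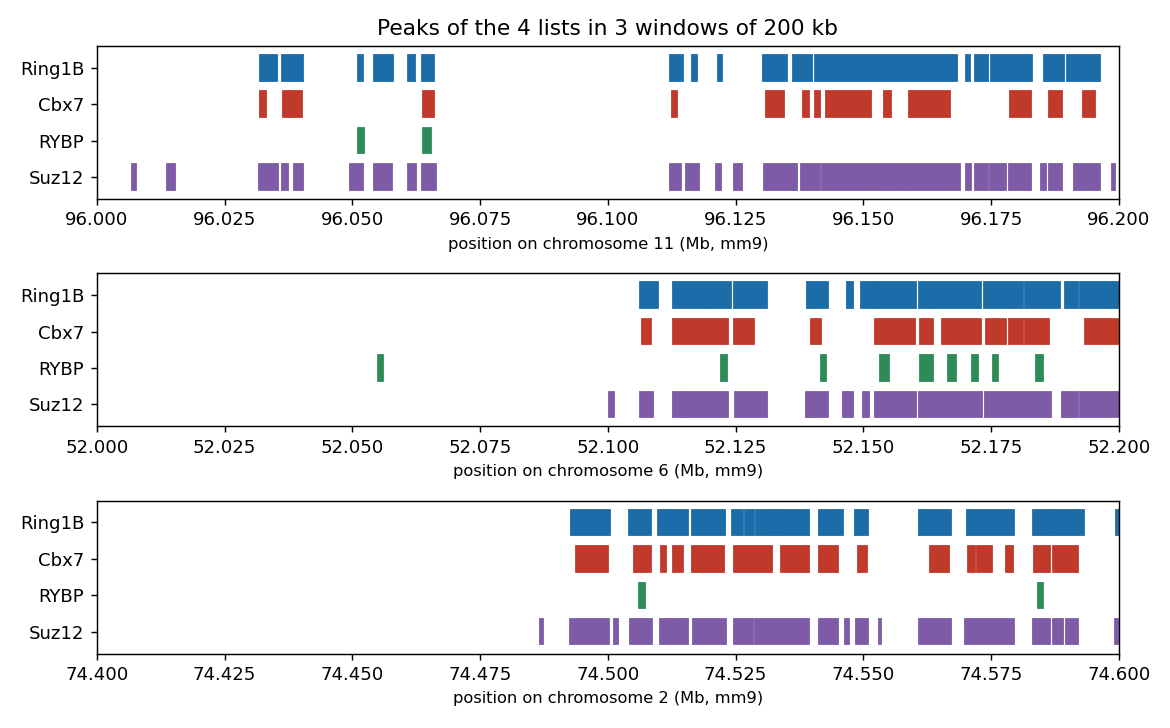
Peaks of the 4 lists (coloured boxes, to scale) in 3 windows of 200 kb on chromosomes 11, 6 and 2 (position in Mb, mm9). Ring1B and Suz12 boxes fill between 34.97% and 41.2% of each window, Cbx7 boxes between 20.5% and 27.2%, and RYBP boxes between 1.10% and 6.17%.

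Among Ring1B peaks with both subunits, the widest lay on chromosome 11 from 85641900 to 85658660 (16.8 kb), where Cbx7 covered 76.5% and RYBP 7.47%. The second, on chromosome 11 from 118895164 to 118910311 (15.1 kb), was covered to 88.2% by Cbx7 and to 30.2% by RYBP. The widest Ring1B peaks with Cbx7 without RYBP, after the 3 intervals above, lay on chromosome 2 from 33483534 to 33501623 (18.1 kb, Cbx7 on 79.2%) and on chromosome 4 from 139376645 to 139392943 (16.3 kb, Cbx7 on 84.2%). The widest with RYBP without Cbx7 lay on chromosome 1 from 172993427 to 173005351 (11.9 kb), with RYBP on 94.3% and Suz12 on 99.1% of it. The next, on chromosome 6 from 114449120 to 114455828 (6.71 kb), carried RYBP on 99.1% and lay in a 1-Mb window with 48 RYBP peaks, 21 Ring1B peaks and 2 Cbx7 peaks. The widest with neither lay on chromosome X from 45693403 to 45699728 (6.33 kb), with Suz12 on 95.02%. Of the 5 widest RYBP peaks, 3 overlapped no other list: chromosome 16 from 3231421 to 3241707 (10.3 kb), chromosome 17 from 3024956 to 3034333 (9.38 kb) and chromosome 4 from 3006031 to 3013773 (7.74 kb). Without read counts, binding at these 3 peaks cannot be told apart from background, which was not tested.

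RYBP peaks were scarce on chromosome X and numerous on chromosomes 11 and 6. Chromosome 11 held 10.2% of RYBP peaks and between 6.35% and 7.49% of the peaks of the other lists. Chromosome 6 held 9.24% of RYBP peaks and between 5.53% and 5.64% of the others. On chromosome X lay 24 RYBP peaks, or 0.349% (95% Wilson interval 0.235 to 0.519%), compared with 3.22% of Ring1B, 3.89% of Cbx7 and 3.03% of Suz12 peaks. The odds of lying on X were 9.50-fold higher for Ring1B than for RYBP peaks (exact 95% interval 6.21 to 15.2, adjusted p = 1.9e-41, two-sided Fisher's exact test adjusted over 6 tests). Differences between the Ring1B, Cbx7 and Suz12 lists were not called in this test (adjusted p from 0.051 to 0.510). On the same Ring1B sites, RYBP was present on 2.67% of 225 peaks of X (1.23 to 5.69%) and on 34.0% of 6754 autosomal peaks (odds ratio 0.053, adjusted p = 2.5e-30, Fisher's exact test over 3 tests). Cbx7 was present on 32.9% and 35.3% (odds ratio 0.897, exact 95% interval 0.666 to 1.198) and Suz12 on 80.0% and 82.0% (odds ratio 0.876, 0.624 to 1.25). Between autosomes the share of Ring1B peaks with RYBP ranged from 25.3% on chromosome 16 to 45.4% on chromosome 6.

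**Figure D5:**
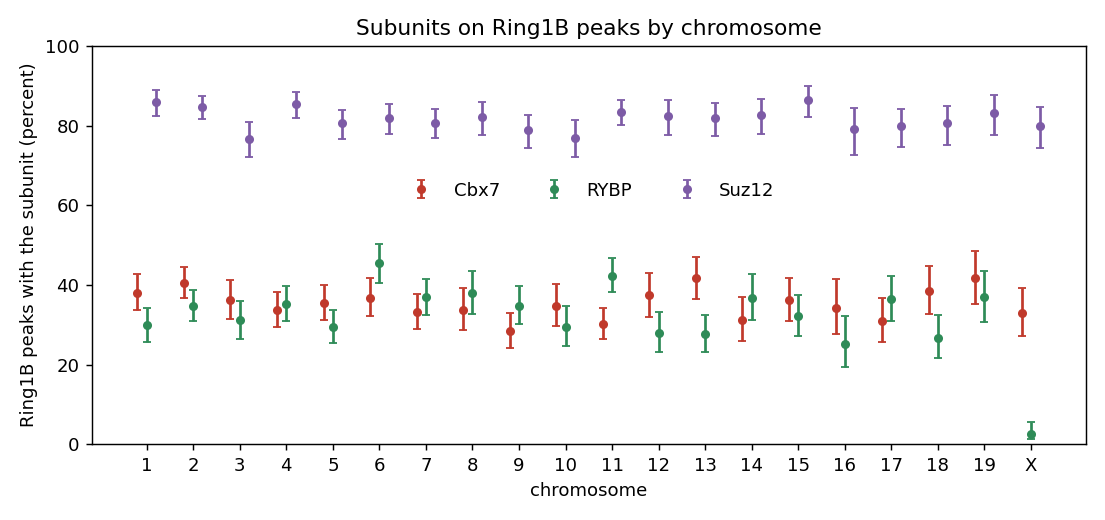
Share of Ring1B peaks with Cbx7, RYBP and Suz12 on each chromosome (percent, linear axis from 0, with 95% Wilson intervals). RYBP lies between 25.3% and 45.4% on the autosomes and at 2.67% on X, where Cbx7 and Suz12 lie at 32.9% and 80.0%.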

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

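The comparison of X between lists was set out before the data were examined, and all other tests in this part were chosen after their results were seen.

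Chromosome X stood out because the difference between lists passed a direct test. The odds ratio for lying on X was 9.50 for Ring1B against RYBP peaks, 11.5 for Cbx7 against RYBP peaks and 0.112 for RYBP against Suz12 peaks. For carrying RYBP, Ring1B peaks of X against autosomal ones had an odds ratio of 0.053.

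RYBP peaks were scarce on X and crowded in a few windows elsewhere, the most crowded being chromosome 17 from 30000000 to 31000000 with 52 RYBP peaks and chromosome 6 from 114000000 to 115000000 with 48. A loss of X reads in all libraries is argued against by the other lists, of which the lowest had 3.03% of its peaks on X. A lower dosage or coverage of X in the RYBP library than in its control and less frequent binding of RYBP on X would both give the low share of 2.67% and cannot be told apart without read counts, and the highest share over 4 equal parts of X, 4.84%, adds nothing because 6 Ring1B peaks of X with RYBP are too few for any part to reach the 25.3% of the lowest autosome. In the chromosome 17 window 2 Ring1B peaks were listed, the median of occupied windows, which argues against a region dense in Polycomb targets, while a segment with more copies in the RYBP library than in its control stays open, since the 3.85% of RYBP peaks on Ring1B follows from that low count. In the chromosome 6 window 21 Ring1B and 34 Suz12 peaks were listed, as such a dense region predicts. A segment with more copies in these libraries than in their control would raise the counts too, so the counts do not decide. Of these Ring1B peaks 2 carried Cbx7, compared with 35.3% of all Ring1B peaks, which was not tested. The 50% of RYBP peaks on Ring1B does not decide on a copy gain in the RYBP library, because Ring1B is dense there too.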

How the results depend on the processing

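Of 177 recomputed values, 101 of them under alternatives planned before the data were examined, 7 changed direction or side of the threshold. All 84 pairwise overlaps and 24 width differences gave the smallest p their tests allow, which says nothing about their size: with equal list lengths the share of Ring1B peaks with Cbx7 moved from 35.3% to 67.7% and that of Cbx7 peaks with RYBP from 28.9% to 16.0%. The 12 comparisons of X kept their side. The 8 list sizes and median widths have no test, and merging peaks within 1 kb moved the Suz12 list from 8054 to 7122 peaks and the RYBP list from 6872 to 6683. Equal list lengths by width, peaks of at least median width, width quintiles and leaving out crowded RYBP windows were chosen after the data were seen. The 7 values concerned 3 results. The odds ratio of Cbx7 and RYBP on Ring1B peaks, 0.945 and not called, was called at 0.840 with peaks within 1 kb (planned), at 0.606 with equal list lengths and at 0.480 within width quintiles. It was not called in the other 4 alternatives, at 0.874 to 0.977, and stayed below 1 in every alternative. The Suz12 difference between peaks with both subunits and with Cbx7 alone was no longer called with peaks of at least median width, at 1.01 points, or within width quintiles, at 0.279 points. The Suz12 difference between RYBP alone and neither turned from -3.42 to 1.40 points with peaks of at least median width and to 8.19 points with equal list lengths; the cause was not tested. Selecting by width removes the narrow Ring1B peaks, of which 39.7% in the narrowest quintile overlapped Suz12 compared with 99.9% in the widest. It also removes narrow RYBP and Suz12 peaks, and at median width narrow Cbx7 peaks. A Ring1B peak can then change class or lose its Suz12 overlap. Width differences were not recomputed on lists chosen by width. Alternatives that hold RYBP to a stricter threshold or rank peaks by score were not run because the lists give no score, nor were those for gene windows. Without read counts, absence of a subunit from a site means absence from its list and not absence of binding, and the Cbx7 list, the shortest, limits every share with Cbx7.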

Other observations

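Of the tests in this part, the odds ratios with an overlap of 1 bp and with peaks within 1 kb were set out before the data were examined. The odds ratio without X, Y and the crowded RYBP windows was set out before its result was seen but after the data were seen. All other tests were chosen after their results were seen.

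Ring1B peaks with Cbx7 without RYBP had close Ring1B neighbours more often than the other classes. Of the Ring1B peaks with Cbx7 without RYBP, 46.2% had another Ring1B peak within 10 kb (95% Wilson interval 43.8 to 48.6%), compared with 31.1% of those with both subunits, 27.9% of those with neither and 18.2% of those with RYBP without Cbx7 (16.3 to 20.2%). The difference between the Cbx7 and the RYBP class was 28.0 percentage points (block interval 23.7 to 32.4), and peaks with both lay 15.1 points below those with Cbx7 alone (difference -15.1, block interval -19.5 to -10.5). A neighbour can be another piece of the same broad region, since merging peaks within 1 kb took the Ring1B list from 6982 to 6284 peaks. The comparison was not repeated on merged peaks or within width quintiles. On chromosome Y the Cbx7 list held 13 peaks, the Suz12 list 5, the Ring1B list 3 and the RYBP list 0. Near the distal end of X, 11 of the 24 RYBP peaks of that chromosome lay between 166407429 and 166631840, where no Ring1B or Cbx7 peak was listed. On chromosome 14 from 4000000 to 8000000, 4 adjoining windows held 102 RYBP peaks, 36 Ring1B peaks and 42 Suz12 peaks but 2 Cbx7 peaks.

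The association of Cbx7 and RYBP over all Ring1B peaks was not called with an overlap of 1 bp, at an odds ratio of 0.945, but was called at 0.840 with peaks within 1 kb, which does not hold width fixed. The value at 1 bp may hide a lower joint occupancy if peak width is a property of the site that favours both subunits, but if the subunits themselves widen the Ring1B peak, holding width fixed gives a negative association where none exists. The pooled odds ratio of 0.480 within quintiles of width therefore decides nothing, and these 2 cannot be told apart because width differed between all classes. Uneven calling of RYBP on X, on Y and in the 21 crowded windows is argued against as the reason that none was called at 1 bp. Without these parts the odds ratio was 0.975 (exact 95% interval 0.874 to 1.09), inside the block interval of the whole set. Uneven calling elsewhere stays open because no test by position was run. With the crowded windows kept, the share of Ring1B peaks with RYBP ranged from 25.3% to 45.4% between autosomes. A biological separation of the 2 forms of PRC1 is a hypothesis that these lists cannot decide without signal values.

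The 4491 RYBP peaks outside Ring1B might be weak calls from a looser threshold. Their share did not vanish among the widest peaks: 48.3% of the widest quintile of RYBP peaks overlapped Ring1B (95% Wilson interval 45.7 to 50.9%), compared with 24.3% of the narrowest quintile, 72.4% of all Suz12 peaks and 98.9% of the widest quintile of Suz12 peaks. Weak calls stay open, because the lists give no strength and the share on Ring1B was higher among wide RYBP peaks. RYBP may also have been called at another stringency than Suz12, and width may not follow strength equally in both lists. Ring1B sites with a listed Suz12 peak that the Ring1B list missed are argued against as the main source by the 5.30% that overlapped Suz12. In the narrowest quintile of Ring1B peaks the share was 39.7%. Sites missing from both the Ring1B and the Suz12 list would also give a low share, so the 5.30% cannot decide on them. These sites, Ring1B sites without Suz12 that were missed, RYBP at other sites, and background shared with the RYBP antibody stay open and were not tested.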
